A study of Bos taurus with 36 samples.

How the data were processed

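Liver RNA from 12 Black Angus steers was measured on 36 single-colour NimbleGen oligonucleotide arrays, 1 array per biopsy. Each steer was biopsied 3 times, so the 36 arrays fall into 6 groups of 6: control and feed-restricted steers at day -14, day +1 and day +14 relative to the return to full feeding. Group, steer number and day were read from the sample titles. Steers are called C1 to C6 (control) and R1 to R6 (restricted) here, in the order of their numbers.

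The value table holds intensity values on a linear scale, 1 per target sequence and array, for 45255 targets, and per the labels the RNA was Cy3-labelled and hybridized in 2 batches. Labelling, hybridization and scanning were done by the NimbleGen core facility, per the labels. Background correction and software are not given in the sources used here. The labels describe a centring of genes by their median inside each batch, but the deposited intensity values are positive and not centred, so that step was not applied to this table. For 18 arrays, deposited probe tables with the intensity of 86063 probes were also read. There, 40808 targets had 2 probes and 4447 had 1. In these 18 arrays the table value was the geometric mean of the target's probes, with a largest gap of 0.000548 on the log2 scale. The sorted probe intensities of the 18 arrays differed by a median of 0.000165 on the log2 scale, which shows that they had been quantile normalized together before deposit.

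Batch membership is not stated per array. As the labels say that the largest component of variation separated the batches, arrays were divided by the sign of the first principal component of the log2 values, which held 88.6% of the variance. The division gave 18 and 18 arrays with 3 arrays of each group and 6 whole steers in each. Batch B is the side whose arrays all have probe tables used here, and batch A is the other. Which was hybridized first is not stated.

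Values were log2 transformed with no offset and no filter. All 36 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with 6 group means, batch as a fixed term and steer as a random block through duplicateCorrelation. The consensus correlation was 0.0253. Moderated statistics came from eBayes, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 45255 targets with a threshold of 0.05. The 9 comparisons were restricted against control at each day, day +1 and day +14 against day -14 within each treatment, and the difference between treatments in these changes.

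The same animals were sampled on every day, so steer numbers pair the arrays. As a check, deviations from the group means within a batch were correlated for the 18 same-steer pairs of each batch. The median r was 0.295 in batch B, with 16 of 18 pairs over 0.1, and 0.0763 in batch A, with 8 of 18 pairs over 0.1. The block follows from the animals and not from this check.

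Differences between steers were tested within each batch by a moderated F test in limma for steer within group means. This test, and the tests on the 2 probes of a target, were chosen after the data were examined. The comparisons, the threshold and 12 alternative settings, besides leaving out each of the 12 steers, were chosen before the data were examined. Another 4 settings were added afterwards, as were refits with array weights that leave out each steer, and 1 that leaves out steer R4 and the day +1 array of steer R3. Among the 12 settings are array weights, which give less weight to arrays that deviate more from the fitted model. Re-normalization of the probe tables used normexp with an offset of 50 and quantile normalization.

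Simulated arrays with the levels and spread of these data were run through the same steps before the real values. For day +14 against day -14 in restricted steers, over 45255 targets, 87% of 100 targets changed by 2 on the log2 scale were recovered, and 40% of 100 targets changed by 1, with 5 false calls. The steer test for batch B, over 45255 targets, recovered 87.5% of 200 targets given steer differences with an SD of 2 on the log2 scale, with 9 false calls. The simulation had independent normal noise and no array-wide deviations. Each target had the same noise SD and the same change in both batches. In the real arrays the median standard error of this day +14 comparison was 0.420 in batch A and 0.251 in batch B. The log2 differences of the 2 batches correlated with r = -0.109, so the recovery may overstate what the real arrays can show.

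The files used here do not pair target identifiers with genes: 0 of the 45255 identifiers were found in the gene table of 37063 entries. Targets are therefore named by identifier, the 24 gene lists and 11 cell type marker lists chosen beforehand were not run, and genes named beforehand could not be looked up. The rule for naming took the targets with the smallest p in each comparison where fewer than 5 passed the threshold. It was narrowed to at most 2 higher and 2 lower targets per comparison. Targets named under array weights or for steer differences were chosen after their values were seen. All named targets were chosen by small p in these same arrays, so like directions over their arrays, steers or batches are no separate support. The number of arrays limits the precision: the median standard error was 0.28 on the log2 scale for a comparison of 2 groups and 0.39 for a difference between treatments in change. Figures were drawn with matplotlib 3.10.9.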

Results

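Liver transcripts were profiled in 12 steers to follow feed restriction and the return to full feeding, called realimentation. Control steers (n = 6) ate freely throughout the 20 weeks. Restricted steers (n = 6) received 60 to 70% of the control intake for 12 weeks and were then fed freely for 8 weeks. Needle biopsies were taken at day -14, in the restriction period, and at day +1 and day +14 of realimentation, which gave 36 arrays in 6 groups of 6.

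The arrays fell into 2 hybridization batches with 3 arrays of every group in each. Median intensity per array was 195 to 202 in batch A and 584 to 640 in batch B. Across targets, pairs of arrays within batch B correlated with a median Pearson r of 0.971 (0.897 to 0.987) on the log2 scale. Pairs within batch A had a median r of 0.877 (0.481 to 0.975), and pairs from different batches had r of 0.049 to 0.383. The batch means correlated across targets with r = 0.226. Of the 453 brightest targets in each batch, 100 were shared, against 4.53 by chance. Targets are not independent replicates, so these correlations describe the arrays only.

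**Figure D1:**
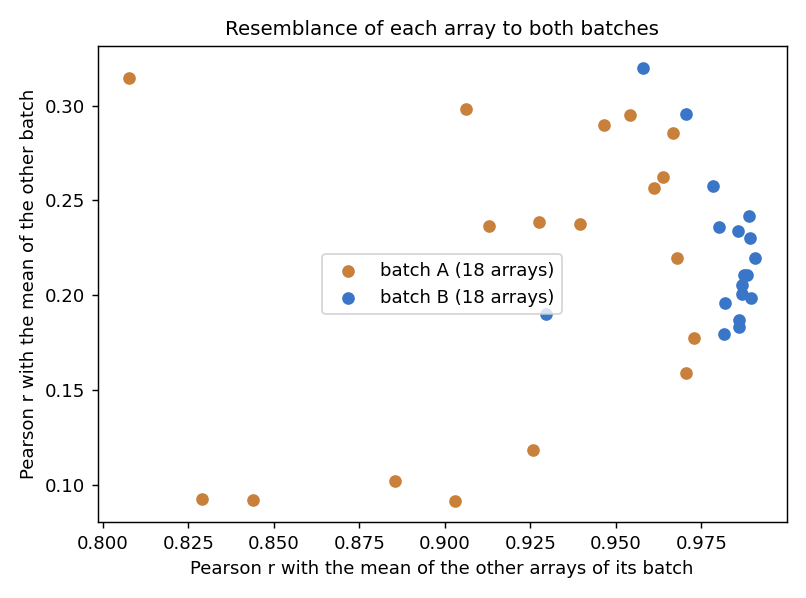
Each point is 1 array; the x axis is its Pearson r across targets with the mean of the other arrays of its own batch, and the y axis its r with the mean of the other batch (no units). Batch B arrays lie at 0.930 to 0.991 on the x axis and batch A arrays at 0.808 to 0.973, while no array exceeds 0.320 on the y axis.

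In the linear model of all 36 arrays, limma called 0 of the 45255 targets at an adjusted p under 0.05 in each of the 9 comparisons. At an unadjusted p under 0.05, where 2263 targets are expected by chance if p-values are uniform, the counts ran from 814 to 8379. With steers or days regrouped, the highest other counts ran from 2315 to 10135 over the 9 comparisons. Lying above or below the nominal 2263 is therefore no test of chance. Log2 differences of the 2 batches correlated across targets with r between -0.109 and 0.069 over the 9 comparisons. Directions of targets at an unadjusted p under 0.05 in both batches varied. For day +1 against day -14, 65 of 87 had the same direction in control steers and 95 of 119 in the difference between treatments. For day +14 against day -14 these were 12 of 24 and 26 of 83. Restricted against control gave 16 of 30 at day -14 and 6 of 21 at day +14. The other comparisons are given below. The standard error within a batch was larger in batch A, with a median of 0.407 for a treatment difference against 0.287 in batch B.

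**Figure D2:**
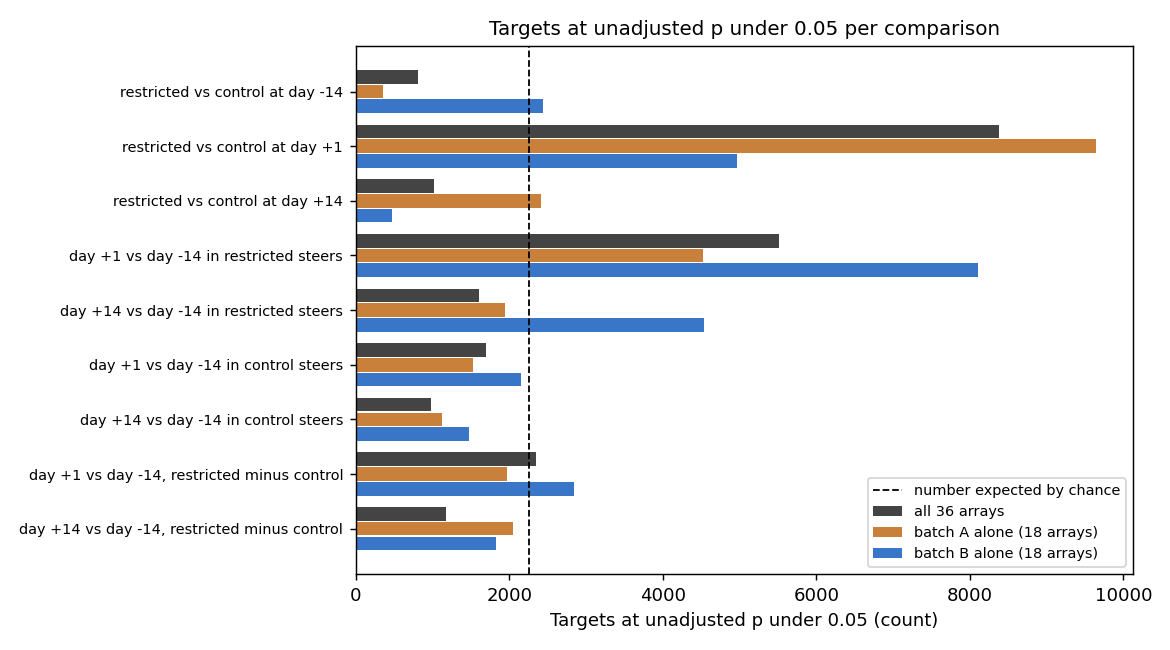
Bars give the number of targets at an unadjusted p under 0.05 in each comparison (y axis), for all 36 arrays and for each batch alone. The dashed line marks 2263, the number expected by chance if p-values are uniform. The treatment comparison at day +1 has 8379 targets with all arrays, 9646 in batch A and 4961 in batch B.

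The comparison of restricted with control steers at day -14 asks how restriction altered liver transcripts. No target passed in limma, with 814 at an unadjusted p under 0.05, of which 348 were higher and 466 lower in restricted steers. The count was 1290 without steer R5 and 1322 without steer C6, and 357 in batch A and 2436 in batch B. It was 4640 with array weights, 7 with no batch term and 823 with each array centred on its median. Re-normalized probe tables of batch B gave 2497, near the 2436 of that batch as deposited. Whether the count lay above the nominal 2263 thus depended on array weights and on the batch used. With quantile normalization 275 were higher and 265 lower. The target with the smallest p, BOVINE0001S00006420, was 1.38 ± 0.26 (SE, n = 6 per group) higher on the log2 scale in restricted steers, with an adjusted p of 0.230, and all 6 restricted arrays lay above the control mean of their batch. In batch B its log2 level was 9.45 ± 0.06 (SD, n = 3) in restricted and 7.30 ± 0.42 (SD, n = 3) in control steers, a difference of 2.15 with an adjusted p of 0.0317 in limma. In batch A the levels were 9.09 ± 0.10 (SD, n = 3) and 8.48 ± 0.37 (SD, n = 3), a difference of 0.60. The lower target with the smallest p, BOVINE0001S00019863, differed by -0.76 ± 0.20 (SE) and did not pass (adjusted p = 1.00). With array weights, 41 targets were higher and 53 lower at an adjusted p under 0.05. That count of 94 ran from 1 to 596 when single steers were left out, the lowest without steer R2 and the highest without steer R4.

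At day +1, 1 day into full feeding, the treatments differed at an unadjusted p under 0.05 in 8379 targets, 3888 higher and 4491 lower in restricted steers, and in 0 targets after adjustment in limma. The balance of directions depended on scaling: with each array centred on its median, 4269 were higher and 4023 lower. The smallest adjusted p was 0.0512, for BOVINE0001S00043974, which was -1.88 ± 0.32 (SE, n = 6 per group) on the log2 scale in restricted relative to control steers. Its difference was -1.71 in batch A and -2.04 in batch B, and all 6 restricted arrays lay below the control mean of their batch. As named targets were chosen by their small p in these same arrays, such agreement is no separate support. BOVINE0001S00007509 differed by -1.46 ± 0.27 (SE), with -1.57 in batch A and -1.36 in batch B. BOVINE0001S00001085 was higher by 1.60 ± 0.30 (SE), by 2.28 in batch A and 0.92 in batch B, and BOVINE0001S00025623 by 1.55 ± 0.30 (SE), by 1.38 and 1.72. These 3 had adjusted p-values of 0.0809, 0.0809 and 0.0894. Of the targets at an unadjusted p under 0.05 in both batches, 1026 against 1057 by chance, 645 had the same direction. Calls depended on single steers: 24 targets passed without restricted steer R4, 10 without restricted steer R6 and 1 without restricted steer R1. The unadjusted count was 5335 without control steer C4 and 4110 with array weights. With array weights 0 targets passed, but leaving out restricted steer R4 as well gave 2932, of which 1463 were higher and 1469 lower. In that refit the batch A array of restricted steer R3 at day +1 had a weight of 2.06, against 0.241 to 0.578 for the other 4 restricted arrays of that day, and without it 0 targets passed. On the first principal component of batch A, the restricted arrays of day +1 lay at 35.7, 118 and 171 (arbitrary units) and the control arrays of that day at -178, -6.33 and 62.5.

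At day +14 the same contrast asks whether a difference remained after 2 weeks of full feeding. No target passed in limma, and 1012 had an unadjusted p under 0.05, 478 higher and 534 lower in restricted steers (692 and 598 with quantile normalization). Within batches the unadjusted counts were 2415 in batch A and 476 in batch B, and with array weights 3829. Leaving out single steers gave 484 without R3, 515 without C4, 630 without C6, 1538 without R4 and 2074 without R6. With array weights 0 targets passed with all steers, 61 without R4, 8 without R6 and 1 without C1. The 95% confidence interval of the difference lay within a log2 change of 1 for 34981 targets, or 77.3%. Larger differences are not ruled out for the rest. The interval is unadjusted and holds for the average over both batches, so it does not bound the difference within 1 batch.

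Within restricted steers, day +1 against day -14 gave 5517 targets at an unadjusted p under 0.05, 2247 higher and 3270 lower at day +1, and none after adjustment in limma. With each array centred on its median the directions turned, with 2938 higher and 2431 lower. The unadjusted counts were 4519 in batch A, 8107 in batch B and 5243 with array weights, and 333 of the 722 targets at that level in both batches had the same direction. BOVINE0001S00042967 was -1.33 ± 0.27 (SE, n = 6) on the log2 scale at day +1 relative to day -14 and lower in 6 of 6 restricted and 4 of 6 control steers, with an adjusted p of 0.310. BOVINE0001S00030303 was 1.68 ± 0.39 (SE) higher, in 6 of 6 steers, with 2.88 in batch A and 0.47 in batch B. In 3 of 6 control steers it was higher too. Without restricted steer R5 the unadjusted count was 2743, and without restricted steer R1 it was 4001. Leaving out only the day +1 array of R1 gave 5221 with both batches and 5032 within batch B, so the 8107 depended partly on that array. With array weights 0 targets passed with all steers and 3082 without restricted steer R4, 1469 higher and 1613 lower. Without the day +1 array of restricted steer R3 as well, 0 passed.

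Day +14 against day -14 in restricted steers gave 0 calls in limma and 1608 targets at an unadjusted p under 0.05, 796 higher and 812 lower, with 1941 in batch A and 4542 in batch B. With each array centred on its median 950 were higher and 706 lower. The total was 5925 with array weights and 4789 from re-normalized probe tables of batch B. Of 216 targets at that level in both batches, 69 had the same direction, and r between the batches was -0.109. BOVINE0001S00022913 was 0.94 ± 0.18 (SE, n = 6) higher on the log2 scale at day +14, and BOVINE0001S00010307 was -1.17 ± 0.26 (SE), each with that direction in 6 of 6 restricted steers and adjusted p-values of 0.478 and 1.00. In control steers 4 of 6 and 2 of 6 had the same direction. In batch B the first went from 10.64 ± 0.17 to 11.69 ± 0.24 (SD, n = 3) and the second from 12.00 ± 0.29 to 10.84 ± 0.22 (SD, n = 3). Both were far dimmer in batch A. There the first went from 5.46 ± 0.05 to 6.30 ± 0.28 (SD, n = 3). The second went from 7.96 ± 0.59 to 6.78 ± 0.29 (SD, n = 3).

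With array weights, 522 targets were higher and 215 lower at day +14 than at day -14 in restricted steers at an adjusted p under 0.05. The first of the higher ones, BOVINE0001S00040204, was 2.12 ± 0.27 (SE) higher on the log2 scale with weights and 1.33 ± 0.34 (SE) without them, and was higher in 5 of 6 restricted and 4 of 6 control steers. The first of the lower ones, BOVINE0001S00023325, differed by -2.61 ± 0.36 (SE) with weights and -1.25 ± 0.43 (SE) without, by -2.44 in batch B and -0.07 in batch A. It was lower in 5 of 6 restricted and 3 of 6 control steers. In restricted steers of batch B its level was 8.80 ± 0.24 at day -14 and 6.36 ± 2.03 at day +14 (SD, n = 3). Weights ran from 0.263 to 1.82 in batch A and from 0.299 to 4.55 in batch B. At day -14 and day +14 they were 1.49 and 2.96 in R1 and 4.55 and 3.30 in R2. They were 0.462 and 0.264 in R3, 1.82 and 1.29 in R4, 0.667 and 0.635 in R5, and 1.87 and 0.339 in R6. The weighted estimates at day +14 thus leaned most on R1 and R2. Without restricted steer R1 or R2, 0 targets passed; 513 passed without R6 and 1255 without R4. The difference from control steers in this change gave 0 calls with array weights, 4275 targets having an unadjusted p under 0.05. That 0 became 71 without steer R4, 19 without C2, 13 without R5 and 1 without R6.

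In control steers, which had no change of feeding, 0 targets passed in limma at either day. Day +1 against day -14 gave 1700 targets at an unadjusted p under 0.05 (1529 in batch A, 2151 in batch B) and day +14 gave 979 (1118 in batch A, 1474 in batch B). Leaving out single steers moved the first to 2924 without C4 and 847 without C6. The second moved to 295 without C5, 510 without C4 and 1938 without C6. With array weights the unadjusted counts were 4357 and 2789. With array weights, 17 targets were higher and 38 lower at day +1 than at day -14. That count of 55 fell to 0 without control steer C2.

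The change in restricted steers minus that in control steers gave 0 calls in limma at both days. At an unadjusted p under 0.05 there were 2351 targets for day +1, with 1965 in batch A and 2839 in batch B, and 1176 for day +14, with 2046 in batch A and 1830 in batch B. The count of 1176 was 547 without C5, 703 without R3 and 2349 without R5. With array weights the count for day +1 was 2986. Within batch B and without the day +1 array of R1, the unweighted count for day +1 was 2235. The 95% interval, unadjusted and for the average over both batches, lay within a log2 change of 1 for 37.3% of targets at day +1. At day +14 the share was 41.0%.

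Individual steers differed in batch B. In limma's moderated F test, 799 of 45255 targets differed between steers of the same treatment at an adjusted p under 0.05, and 10571 targets, 23.4%, had an unadjusted p under 0.05. In batch A the count was 0 at an adjusted p under 0.05 and 836, or 1.85%, at an unadjusted p under 0.05. Over all steers of batch B, control and restricted together, steer means spanned more than 1 on the log2 scale in 699 of the 799 targets and more than 3 in 96. These spans include differences between treatments, which the F test removes. BOVINE0001S00022615 had a log2 level of 12.82 ± 0.21 (SD, n = 3 biopsies) in steer R2, 12.63 ± 0.14 in steer R6 and 12.75 ± 0.13 in steer C3. Its level was 8.50 ± 0.24 in steer R1, 5.02 ± 0.29 in steer C2 and 4.68 ± 0.05 in steer C1. BOVINE0001S00028201 was at 9.84 ± 0.19 (SD, n = 3 biopsies) in steer C3 and at 4.15 to 4.67 in the other 5 steers. BOVINE0001S00031655 was at 6.73 and 6.84 in control steers C3 and C1 and at 11.46 to 11.80 in the other 4. The count of 799 was 261 without steer C1, 264 without steer C3, 431 without steer R6, 441 without steer R1 and 531 without steer C2.

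**Figure D3:**
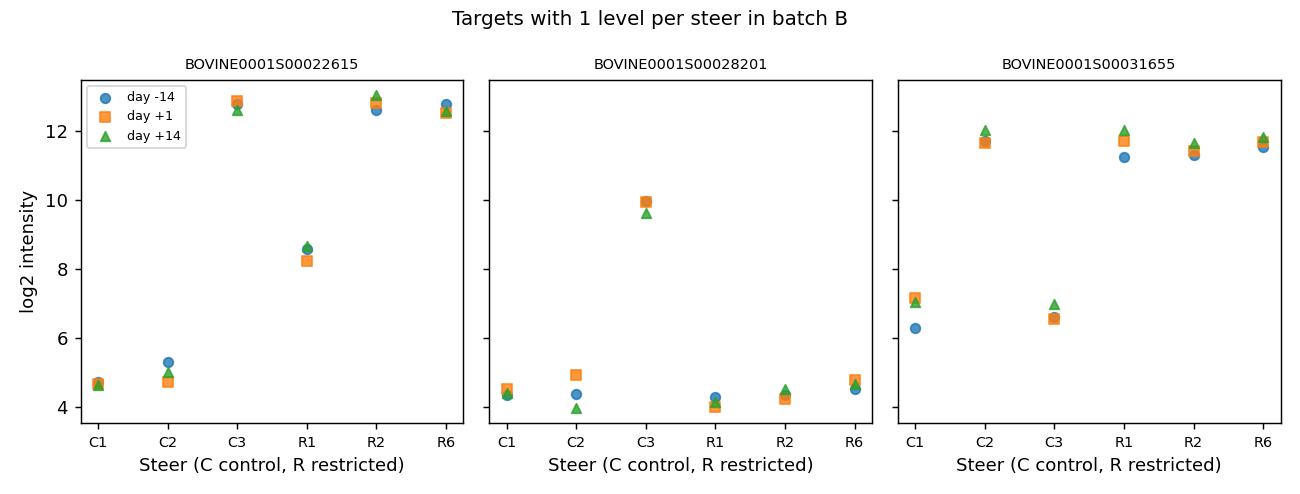
Log2 intensity (y axis) of 3 targets in the 18 arrays of batch B, by steer (x axis, C control and R restricted); each point is 1 biopsy and the marker shape gives its day. The 3 biopsies of a steer lie together while steers differ by up to 8.14 on the log2 scale.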

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

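Tests of the array of steer R1, of agreement between batches, of feature order, of the first component of batch A and of single-probe noise were chosen after the result was seen; the other tests here were set before their results were known. Of 78 groups of 6 values examined, 6 held a value far from the rest, where chance gives about 1 in 20.

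By its correlation with the mean of its own batch, taken relative to the batch average, control steer C4 at day +1 lay at -0.0923 while the other 5 arrays of the group lay between -0.0185 and 0.00803. Restricted steer R4 at day -14 lay at 0.0514, against 0.00121 to 0.0104. Relative to the batch mean on the log2 scale, BOVINE0001S00006420 was at 0.33 in control steer C5 at day +1 and at -0.73 in restricted steer R3 at day +14. BOVINE0001S00042967 was at 0.77 in control steer C3 at day +1, and BOVINE0001S00025623 at 0.84 in restricted steer R6 at day +14.

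The 8379 targets at an unadjusted p under 0.05 between treatments at day +1 exceed the nominal 2263. Of 100 splits of the steers balanced over the batches, 9 gave as many, the highest other one 10135, so chance cannot be excluded. One array, restricted steer R1 at day +1, resembled its batch least in batch B (r = 0.930), but 8673 targets were at that level without it, which argues against that array as the cause. A treatment effect seen by both batches stays open: their log2 differences correlated across targets with r = 0.0237, and 79 of 200 splits gave an r as high. Array differences in batch A stay open too and were not tested for this pattern: the component that followed resemblance to batch B (r = 0.829) ran partly with treatment at day +1, although batch B alone had 4961 such targets.

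Batch A resembled batch B weakly and gave no steer differences. A shifted order of its features is argued against, as the batch means correlated best at an offset of 0 (r = 0.226, next highest 0.0768). Exchanged steer labels are argued against as the whole cause: targets that differed between steers in batch B had a median SD percentile of 50.3 in batch A among targets of like level, although noise in batch A may hide their spread. Hybridization differences between arrays remain a candidate explanation that the test could not decide. Over the 18 arrays of batch A, the first principal component held 45.3% of the variance. It followed resemblance to batch B with Pearson r = 0.829 (permutation p = 4e-05) and Spearman rho = 0.777 (permutation p = 0.00024). Without the 2 farthest arrays r was 0.782. The component and the resemblance come from the same values, so a high r was likely whatever the cause. The permutation also treated arrays of the same steer as independent, so its p-values do not measure support for hybridization differences. No biological explanation was tested.

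With array weights, 737 targets were called between day -14 and day +14 in restricted steers. Of 32 ways to swap the days within steers, 1 gave as many, the real one; swapping R3, R4 or both gave 669, 677 and 674, R5 alone 352, R6 alone 119, R5 and R6 80, and R3 and R6 0. No split that set steer R2 against steer R1 gave more than 1 call, but with these 2 in agreement the count still ran from 0 to 737. As this was the comparison with the most weighted calls of the 9, chance is not taken as excluded although the share is under 0.05. Noise of single probes was not decided for the called targets, as the test took all targets with 2 probes. The changes of the 2 probes of a target correlated with r = 0.532 in batch B. In the other 9 splits of the 6 arrays r was 0.284 to 0.405, too few splits for a share under 0.05. As every split gave a raised r, the test could hardly have come out for noise. A change over time in all steers stays open (r = 0.350 between the weighted changes in control and restricted steers over the called targets). Between batches, 54.0% of the 2139 targets called in batch B alone with weights had the same direction in batch A, without weights r between the batches was -0.109, and 69 of the 216 targets at an unadjusted p under 0.05 in both had the same direction.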

How the results depend on the processing

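The added settings here were chosen after the data were examined: within-batch medians set to 0, leaving out the array of restricted steer R1 at day +1 (with both batches or within batch B), array weights within batch B, array weights without single steers or without steer R4 and the day +1 array of R3, and all settings of the steer test. Gene list alternatives were not run. The causes of the changes below were not tested. Counts at an adjusted p under 0.05 were 0 in limma for every comparison with no steer block, with a fixed steer block where it could be fitted, with no batch term, within batch A, with arrays centred or quantile normalized, with only the arrays compared and with robust eBayes; the block changed no call.

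Restricted against control at day -14 gave 94 calls with array weights, 2 within batch B, 2 from re-normalized probe tables, 2 within batch B without the R1 array, 176 within batch B with array weights, and 0 to 1 without single steers. At day +1 it gave 1 without the dimmest targets, 1 with medians set to 0, 1 without the R1 array, 2 within batch B without that array, and 0 to 24 without single steers. At day +14 it gave 1 from re-normalized probe tables and 4 within batch B with array weights. Day +1 against day -14 gave 1 call within batch B without the R1 array in restricted steers and 1 in the difference from control steers. In control steers it gave 55 with array weights and 30 within batch B with them. Day +14 against day -14 in restricted steers gave 737 with array weights, 1 from re-normalized probe tables and 2139 within batch B with array weights.

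With array weights and single steers left out, restricted against control gave 1 to 596 calls at day -14 (94 with all steers), 0 to 2932 at day +1 (0) and 0 to 61 at day +14 (0). In restricted steers there were 0 to 3082 for day +1 (0) and 0 to 1255 for day +14 (737), and in control steers 0 to 95 for day +1 (55). The difference between treatments in change gave 0 to 71 at day +14 (0), and the other 2 comparisons 0 throughout. The highest count came without R4, except for the 95, without C4. Leaving out the day +1 array of R3 besides R4 gave 656, 0 and 33 for the treatments by day, 0 and 1321 in restricted steers, 36 for day +1 in control steers and 57 for the difference at day +14; the 2932 and 3082 thus rested on that array. The 8379 targets at an unadjusted p under 0.05 at day +1 became 11 with no batch term and 4110 with array weights. With only the arrays compared they were 5304, and without single steers 5335 to 10019. Within batch B the count was 4961, and 5041 from the re-normalized probe tables of that batch. It was 3445 within batch B without the R1 array and 3794 within batch B with array weights. The 799 targets that differed between steers became 261 to 698 without single steers and 730 to 1053 otherwise. Of the 328 refits of named targets, none changed direction and 23 passed the threshold. These targets were chosen by small p in the same arrays, with or without array weights, so a kept direction is no separate support. Signal over background is not given, so what dim targets can show is unknown.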

Other observations

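The probe test for steer differences was set before its result was known, while the steer test itself was chosen after the data were examined. In batch B, 799 targets differed between steers of the same treatment. The test removes the group mean of each day, so it does not show that the level of a steer stayed constant over the 3 biopsies. Of 100 assignments of arrays to steers within groups, only the real one (1 of 100) called as many, and the highest other called 133. This argues against chance in batch B, with the limit that the steer test was chosen after the data were examined. In batch A the steer test called 0 targets. A hypothesis is that inherited differences between animals set the steer levels, either in the transcript or in the sequence under a probe. Inheritance itself was not tested. Of the 699 such targets with 2 probes, 66.2% had steer levels that correlated by more than 0.8 between the probes, against 29.4% of all targets with 2 probes and 4.01% for probes of different targets, which may be partly raised because targets were chosen on the mean of both probes. The share lies between the bounds set for a difference in the transcript (over 75%) and for one under a single probe (under 25%, a bound below the 29.4% of all targets), so these cannot be told apart for the set.

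Other splits of the arrays were run for every comparison with limma, counting targets at an unadjusted p under 0.05; in none of these 9 could chance be excluded. Among 100 balanced splits of the steers, 37 gave as many as the 814 at day -14 (highest other 2315) and 69 as many as the 1012 at day +14 (6305). For the difference between treatments in change, 35 gave as many as the 2351 at day +1 (5103) and 51 as many as the 1176 at day +14 (5121). Among 32 swaps of days within steers, 3 gave as many as the 5517 for day +1 in restricted steers (6193), 19 as many as the 1608 for day +14 (5022), 15 as many as the 1700 for day +1 in control steers (5557) and 16 as many as the 979 for day +14 (3193). With array weights, 10 of 100 splits called as many as the 94 at day -14 (387), and 2 of 32 swaps as many as the 55 for day +1 in control steers (59). With array weights and without steer R4, 1 of 100 splits, the real one, called as many as the 2932 between treatments at day +1 (2216), and 1 of 16 swaps as many as the 3082 for day +1 in restricted steers (8), too few for a share under 0.05. Both were run because these counts were the highest of all refits, and both counts were 0 without 1 further array, so for the 2932 chance is not taken as excluded although the share is under 0.05. Some splits called several times the real count, and the cause of this was not tested.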
